A study of Homo sapiens with 4 samples.

How the data were processed

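Total RNA of 2 Meg-01 RUNX1 knockdown RNAs and 2 negative control RNAs was amplified to aminoallyl RNA, coupled to a green or a red Alexa dye and hybridised to Agilent whole human genome oligonucleotide arrays, per the labels' protocols. Per the file headers, the 4 arrays lay on 1 slide, were read in 1 scan and were quantified with Agilent Feature Extraction 9.5.3.1, with probe positions on hg17 (NCBI35). The deposited scanner files hold, per spot, the raw intensity and the local background intensity of each channel, and the intensity after the scanner software's own background subtraction and dye normalization, per the file headers. They also hold the log10 ratio of red over green, per the file headers. The deposited value table of the series holds log10 ratios. Set against the scanner files, it equals the scanner software's log ratio with the sign of the swapped arrays turned to knockdown over control (r = 1, maximum difference 4.99e-06). Its scale and direction are thus known and no centring was added, with column medians of 0 on 3 arrays and 0.00358 on the swapped array of pair 2. No depth applies to arrays, and their number limits the precision.

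Raw spot intensities were background-corrected with normexp (offset 50) and normalized within each array by loess, with control spots given weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as outliers were left out and saturated spots were kept. Log2 ratios of the swapped arrays were turned so that every ratio is knockdown over control. Spots of a probe were averaged. Of 41000 probes, 23434 were named through their RefSeq accession, 2317 through a current symbol and 1043 through an older symbol of 1 gene, using a table of the GRCh38.p14 assembly for names only. The other 14206 probes were not matched and stayed out of the gene-level tests. A probe was tested if knockdown or control RNA was well above background on all 4 arrays. The brightest such probe stood for its gene, which left 12793 genes. Other probes of the named genes were compared with it: of 35 named genes with another tested probe, 6 had a probe of opposite sign and 7 a probe more than 1 log2 unit away. A gene not above background in an RNA on every array has only a bound there. It was computed from the mean channel levels after loess and Aquantile scaling, with the lowest level well above background, or the probe's own if higher, standing for the dim RNA.

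The 2 arrays of a pair hold the same 2 RNAs and were averaged, so n = 2 pairs. Pair means were tested against 0 with lmFit and eBayes, 2-sided, and p-values were adjusted with the Benjamini-Hochberg method at 0.05. The dye effect cancels in each pair mean. With 1 residual degree of freedom per gene, the test leans on the spread shared across genes (3.62 prior degrees of freedom, prior SD 0.0575). Samples were mapped from the labels' pair numbers and dyes. The numbers join a knockdown and a control on an array, so the pairing is part of the ratio itself. Because there is a single group of ratios, no comparison between groups, no test of other splits of the samples and no test for outlying samples could be made. With 1 slide and 1 scan, neither could be tested as a batch.

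Before the data were examined, 22 gene lists and the rule for named genes were fixed. RUNX1, RUNX2, RUNX3, CBFB and PIK3CD are always named. So are the 10 largest rises and 10 largest falls past the threshold with the same sign on all 4 arrays, the brighter RNA above background and unsaturated, and a proper gene symbol. Up to 3 members per list that passed with the largest change are named too. Some genes that this rule names are not reported here, while list counts and set tests include them. Other genes named beside them, such as ALAS2, KLF1, CA2, ITGB3, GP1BA, GP6, CIITA, HLA-DQB1, DCK, CDKN2A, CDKN2C and FDFT1, were chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01 between genes, then with an estimated correlation and with fry, all in limma. At the preset correlation camera compares a list's genes with the other genes, so its p-values do not measure replication over the pairs.

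The functions were tested on simulated arrays with 200 genes changed among 12793 in the same design of 2 pairs. Of the changed genes, 98.5% at 1.5-fold, 100% at 2-fold and 100% at 4-fold were called in the right direction. A further 26 genes were shifted together as a list, which passed, and 0 of the 22 other lists did. Noise was drawn for each gene on its own, so list calls among correlated genes were not checked. Its variance came from the prior fitted to the real data, with no deviation shared by the pairs. The shares called and falsely called are thus partly built in and hold for such noise only. Of 242 calls over all genes, 18 (7.44%) were genes simulated without a change of either kind. Alternatives covered the background correction, the normalization, the filter, the variance trend, the use of 4 arrays in place of pairs, the rule for probes, the deposited value table, either dye orientation, each pair alone and, for the counts of genes only, a test against a 1.2-fold change.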

Results

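Gene expression was measured in Meg-01, an established human megakaryoblastic leukaemia cell line, after RUNX1 had been lowered with a lentiviral short hairpin RNA. RUNX1 (also called AML1) is a DNA-binding transcription factor of blood cell formation that works with the partner protein CBFB. The knockdown RNA came from soft-agar colonies picked for low RUNX1 after puromycin selection, and the control RNA came from a pool of cells transduced with a negative control. Knockdown and the derivation of a line from a colony therefore went together in every comparison. Some labels call the treated cells a knockout, but the series title and the culture protocol describe a knockdown. Each of 2 knockdown RNAs was hybridised with a control RNA of the same number on 2 two-colour arrays, with the dyes exchanged on the other array, so that 4 arrays gave 2 pairs of RNAs. The series design calls the RNAs of each kind biological replicates. The labels do not say whether the control RNAs came from separate cultures, or whether knockdown RNAs 1 and 2 came from different colonies. The p-values of single genes thus measure the spread between these pairs, which can be partly technical. Those of gene lists from camera at the preset correlation compare genes with other genes and do not measure that spread. Between 67.4% and 84.8% of the spots were well above background per channel and array, with the highest shares on the dye-swapped array of pair 2. The small number of arrays limits the precision.

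RUNX1 itself was lower in knockdown cells on all 4 arrays. Its log2 ratio of knockdown over control was -0.88 ± 0.17 (SD, n = 2 pairs), a 1.83-fold fall (adjusted p = 0.00164), with -0.997 in pair 1 and -0.75 in pair 2. This value came from the brighter RUNX1 probe, at hg17 chromosome 21, 35082261 to 35082320, on the minus strand. A second, dimmer RUNX1 probe at 35127650 to 35127708 had a log2 ratio of 0.01, and the mean over the probes was -0.43. No gene annotation of that genome build was used here, so neither probe was placed in an exon. The related factors RUNX2 and RUNX3 and the partner CBFB did not pass the test, with log2 ratios of 0.05, 0.03 and -0.02, but RUNX2 passed with Agilent's processed signals (0.27, adjusted p = 0.04). RUNX1T1, a corepressor gene known as a fusion partner of RUNX1 in leukaemia, rose 2.94-fold (log2 ratio 1.56 ± 0.06, SD, n = 2, adjusted p = 0.000172). Of the 7 RUNX and core binding factor genes measured, 1 rose, 1 fell and 5 did not pass. Adjusted over the list alone, 1 rose and 2 fell, and the list as a set did not pass (adjusted p = 0.84). Its median was -0.02 and its mean 0.07.

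Among the largest rises were those of SEMA6D, a semaphorin, by 13.3-fold (log2 ratio 3.73 ± 0.13, SD, n = 2) and of BCHE, butyrylcholinesterase, by 9.08-fold (3.18 ± 0.16). DCAF12L1 rose 7.64-fold, the cancer-testis gene MAGEA1 7.56-fold and the mast cell protease gene CPA3 by 2.59 on the log2 scale. PRUNE2, DOCK10, the platelet protein gene MMRN1 and CALN1 followed, with log2 ratios of 1.89, 1.86, 1.83 and 1.72. Among the deepest falls were those of MS4A3, a gene of myeloid progenitors and basophils, by 11.8-fold (-3.56 ± 0.03), and of the axon guidance receptor ROBO2, by 9.53-fold (-3.25 ± 0.18). TSPYL5 fell 8.69-fold, the neuropeptide gene NMU 8.51-fold and the progenitor antigen CD34 7.32-fold. LTBP1, EPB41L3 and EGLN1, an oxygen-dependent prolyl hydroxylase, fell, with log2 ratios of -2.81, -2.72 and -2.71. The adjusted p of these genes lay between 9.38e-05 and 0.000793. A further tested probe of each of CD34, ROBO2 and EGLN1, well above background in both RNAs, had a ratio of the same sign but over 1 log2 unit smaller, for example -0.85 for EGLN1. Further probes of SEMA6D, DCAF12L1 and DOCK10 had ratios above 0, but control RNA was well above background on at most 1 of 4 arrays there, so their size is not known.

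Across the 12793 genes tested, 1735 were higher and 2318 were lower in knockdown cells (limma with Benjamini-Hochberg adjustment at 0.05). All of these 4053 genes had the same sign in both pair means, and 3778 had it on all 4 arrays. In the others the sign differed between arrays. Most changes were small, with a median size of 0.27 on the log2 scale among called genes. A change of 2-fold or more in the same direction in both pairs was seen for 198 genes, of which 43 were higher and 155 lower, and 0 genes changed that much in opposite directions. The count of 198 became 451 with Agilent's processed signals, 105 with no background subtraction and 304 with every probe tested on its own. Lower genes made up 57.2% of the calls. They made up 48.2% with Agilent's processed signals and with the deposited value table (1917 higher and 1786 lower in each). When arrays were centred on their median in place of loess they made up 34.5%. That centring moved the median of all genes from 0.00 to 0.08. Without the swapped array of pair 2, a choice made after seeing the data, 1081 genes were higher and 1894 lower.

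**Figure D1:**
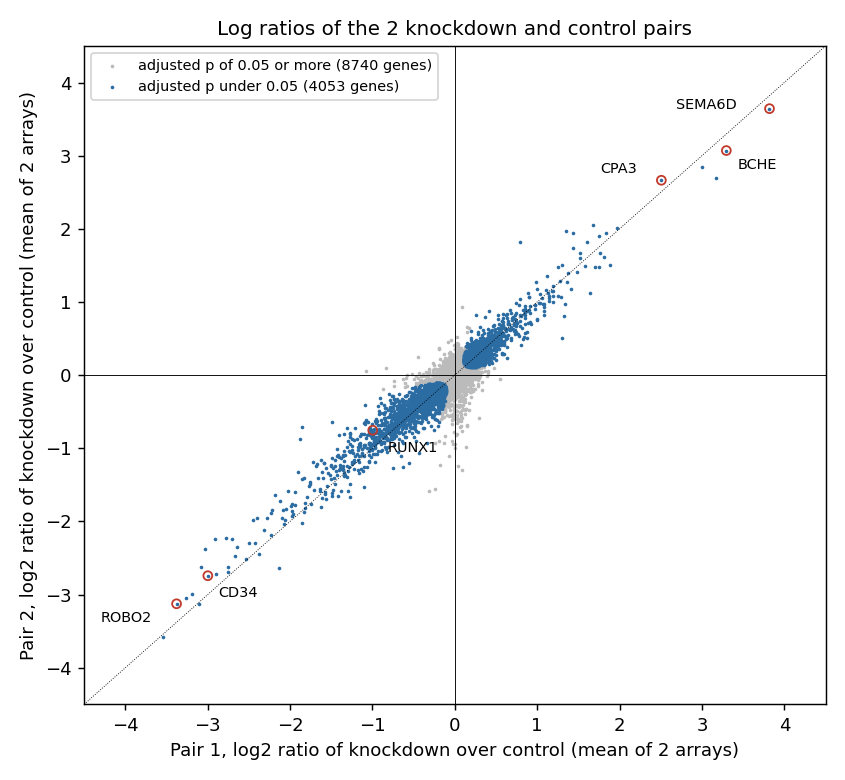
Each point is a tested gene, with its log2 ratio of knockdown over control in pair 1 on the x axis and in pair 2 on the y axis, each the mean of 2 dye-swapped arrays; blue points passed the adjusted p threshold and the dotted line marks equal values. RUNX1 lies at -0.997 and -0.75, and points far from 0 include SEMA6D (3.82 and 3.64) and ROBO2 (-3.38 and -3.13).

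The log ratios of the 2 pairs were correlated across genes (Pearson r = 0.92, Spearman rho = 0.81), where genes are not independent replicates. The covariance was 0.0918. Simulated unchanged knockdowns sharing a single control RNA gave a mean r of 0.47 and a covariance of 0.0099. The arrays held 2 control RNAs, unlike the simulation. The simulated control's variance (0.00991) was estimated from the difference between them, which leaves out what they share. The simulated covariance restates this input. This left 0.0819 of the observed covariance, a remainder that can still hold a deviation shared by both control RNAs. The simulation gave each knockdown its own deviation, so a difference of colony from pool that both knockdown RNAs share would stay in this remainder. A difference of 2-fold or more between the pairs was seen for 12 genes.

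Erythroid genes were lower in knockdown cells. Of the 26 measured, 22 fell, 1 rose and 3 did not pass, with a median log2 ratio of -0.69 (camera adjusted p = 5.85e-11; adjusted p = 0.917 with an estimated correlation). Glycophorin B (GYPB) fell 5.95-fold and beta globin (HBB) fell 5.67-fold (-2.50 ± 0.39, SD, n = 2). The heme synthesis enzyme gene ALAS2 had a log2 ratio of -1.31 and the erythroid transcription factor KLF1 -0.19, both past the threshold. Carbonic anhydrase CA2 was the member that rose, with a log2 ratio of 0.26. The camera p-value at the preset correlation compares these genes with the others and does not measure replication over the 2 pairs. Adjusted over the list alone, 23 fell and 1 rose. Globin probes resemble each other in sequence, as do those of the glycophorins, so values within these families are not fully separate.

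Megakaryocyte and platelet genes went both ways. Of 21 measured, 10 fell, 3 rose and 8 did not pass, and adjusted over the list alone 11 fell and 4 rose. LTBP1, the scavenger receptor CD36 (-1.50 ± 0.14, SD, n = 2) and the protein kinase C substrate PLEK (-0.98 ± 0.01) fell most, while integrin beta 3 (ITGB3, 0.49), GP1BA (0.43) and GP6 (0.41) rose. The median was -0.14 and the set test did not pass (adjusted p = 0.175), but it passed with Agilent's processed signals (adjusted p = 0.0396) and with median centring (adjusted p = 0.000759).

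Genes of antigen presentation were lower. Of 9 MHC class II genes measured, 8 fell and HLA-DQB1 did not pass (-0.29), with a median of -0.47 (camera adjusted p = 9.37e-05; adjusted p = 0.917 with an estimated correlation). HLA-DRA fell 3.86-fold (-1.95 ± 0.03, SD, n = 2) and HLA-DRB5 1.83-fold. HLA-DPA1 fell with a log2 ratio of -1.26, but its knockdown RNA was well above background on only 2 of 4 arrays. The class II transactivator CIITA fell by 0.18 on the log2 scale, with knockdown RNA well above background on 3 of 4 arrays. Of 12 MHC class I genes, 8 fell and 4 did not pass, with a median of -0.18 (camera adjusted p = 0.00564; adjusted p = 0.917 with an estimated correlation). HLA-C had a log2 ratio of -0.55, HLA-G -0.48 and the peptide transporter TAP1 -0.39. HLA-E, counted as a fall, was below 0 only with knockdown in the green channel (-0.32 and -0.31, against 0.04 and 0.03 in the red). Further HLA-G probes, at -0.01 and 0.01, were well above background on at most 1 of 4 arrays in either RNA. Adjusted over the list alone, 9 class II and 9 class I genes fell. The class I call ended with median centring (adjusted p = 0.299), on the arrays with knockdown RNA in the red channel alone (0.499) and without the swapped array of pair 2 (0.173). HLA genes are close copies of each other, and their probes may not tell alleles or neighbours apart.

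**Figure D2:**
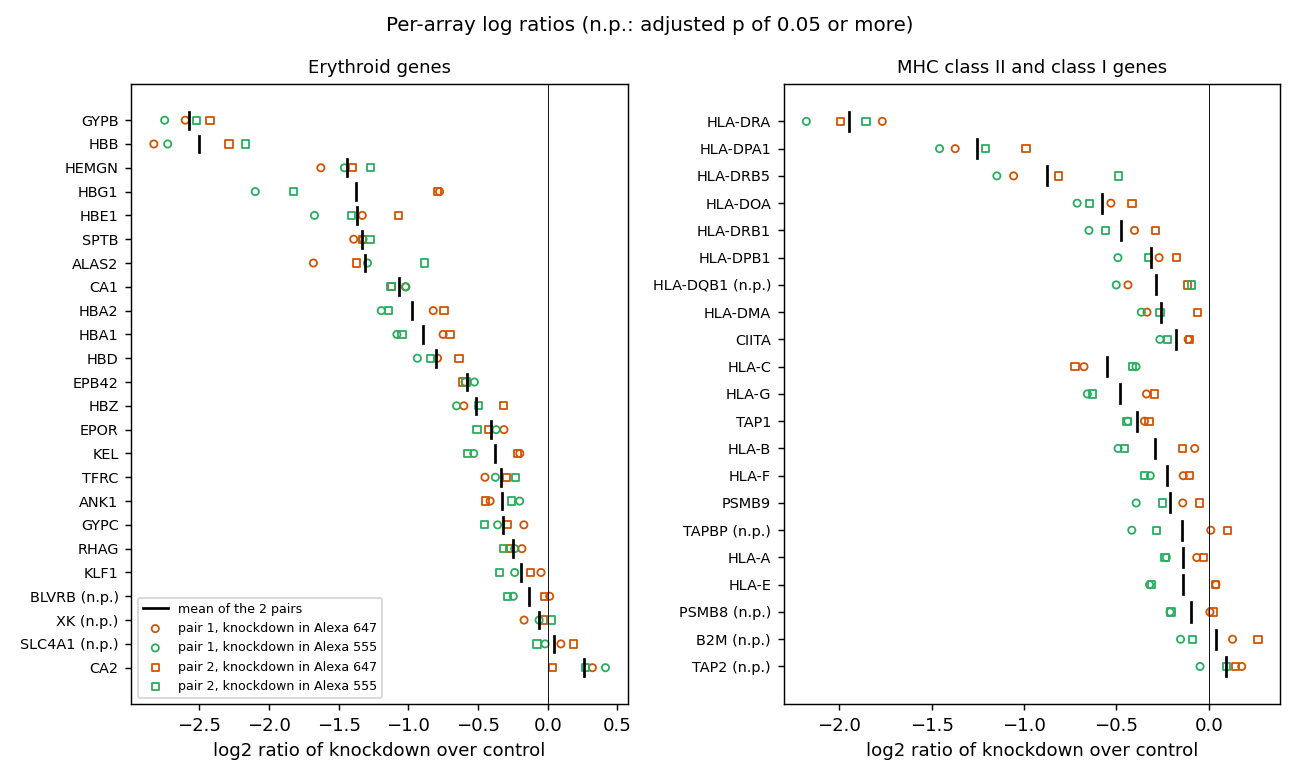
Log2 ratios of knockdown over control for the erythroid genes (left) and the MHC class II and class I genes (right), with a symbol for each of the 4 arrays (circles for pair 1, squares for pair 2, orange for knockdown in the red channel, green for knockdown in the green channel) and a bar at the mean of the 2 pairs. Among the erythroid genes drawn, GYPB (-2.57) and HBB (-2.50) lie farthest to the left, and HLA-DRA (-1.95) among the MHC genes; genes not reported here are not drawn; n.p. marks genes that did not pass.

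Cell cycle genes shifted slightly downward. The deepest falls were those of CCND2, by 2.80-fold (-1.49 ± 0.14, SD, n = 2; further probes at -1.20 and -1.31), CCND1, by 2.67-fold (-1.42 ± 0.21; further probes at -0.82 and -0.90), and CDK6, by 2.35-fold (-1.23 ± 0.03; a further probe at -0.37, with knockdown RNA well above background on 2 of 4 arrays). Of 47 measured genes, 13 fell, 2 rose and 32 did not pass, and the counts of rises and falls were the same when adjusted over the list alone. The 2 that rose were the cyclin-dependent kinase inhibitor genes CDKN2A and CDKN2C, each at 0.19. CDKN2A had log2 ratios of 0.59 and 0.54 with knockdown in the red channel but -0.20 and -0.18 with knockdown in the green channel, so its direction depended on the dye. The median was -0.05 (camera adjusted p = 0.024; adjusted p = 0.917 with an estimated correlation). With median centring the median was 0.07 and the call was lost (adjusted p = 0.266), as it was on the arrays of either dye orientation alone (adjusted p = 0.0778 and 0.0713) and without the swapped array of pair 2 (0.0563).

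Cholesterol synthesis and uptake genes were higher. Of 23 measured, 11 rose, 1 fell and 11 did not pass, with a median of 0.15 (camera adjusted p = 0.000896; adjusted p = 0.917 with an estimated correlation), and 12 rose and 1 fell when adjusted over the list alone. The sterol carrier STARD4 rose 1.34-fold (0.42 ± 0.19, SD, n = 2) and INSIG1 1.23-fold (0.30 ± 0.07). FDFT1, the squalene synthase gene, fell by 0.24, and it lies in a stretch of chromosome 8 whose tested genes had a median of -0.25.

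Genes of the PI3K, AKT and mTOR pathway were of interest because RUNX1 has been studied in this leukaemia in relation to PI3K signalling and drug response. PIK3CD, which encodes the p110 delta catalytic subunit of PI3K, had a log2 ratio of -0.26 ± 0.02 (SD, n = 2, adjusted p = 0.00875). A dimmer PIK3CD probe had 0.02, and the mean over probes was -0.12 and did not pass (adjusted p = 0.0931). Of 35 pathway genes measured, 8 rose, 4 fell and 23 did not pass, and adjusted over the list alone 10 rose and 6 fell. IRS2, an insulin receptor substrate, rose 1.82-fold (0.86 ± 0.17), although a further tested IRS2 probe had 0.04, and PIK3C2B had a log2 ratio of 0.58, past the threshold, while FOXO3 fell 1.34-fold. The FOXO3 call ended with Agilent's processed signals (adjusted p = 0.0649) and with every probe tested on its own (0.0581), while its log2 ratio stayed at -0.42 in both. The set did not pass (median 0.07, adjusted p = 0.106). Among 26 genes of nucleoside and cytarabine metabolism, 3 rose and 2 fell, 21 did not pass, and the counts of rises and falls were the same adjusted over the list alone. The ecto-nucleotidase NT5E (-0.49), the nucleotidase NT5C2 (0.27) and the ribonucleotide reductase subunit RRM2 (-0.21) changed most. Further NT5E probes had -0.21 and -0.19, with knockdown RNA well above background on 3 of 4 arrays. RRM2 lost its call with median centring (-0.07). Deoxycytidine kinase DCK, which activates cytarabine, did not pass (0.11). The median was 0.02 and the set adjusted p was 0.489. In the BCL2 family and apoptosis list, 8 of 35 genes rose, 7 fell and 20 did not pass, and 10 rose and 8 fell adjusted over the list alone. MCL1 (-0.53) and PMAIP1 (-0.49) fell and BCL2 rose (0.31), although a further BCL2 probe had -0.05. The median of 0.01, the mean of -0.01 and a set adjusted p of 0.822 gave no common direction.

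Stem and progenitor genes went both ways, with 6 of 20 higher, 5 lower and 9 that did not pass. CD34 fell, while MECOM, a regulator of blood stem cells, rose 1.54-fold (0.62 ± 0.01, SD, n = 2) and FLI1, a megakaryocytic ETS factor, rose 1.41-fold. Further tested MECOM probes had 0.62, 0.30 and 0.17, the last with ratios below 0 on the arrays with knockdown in the green channel. Adjusted over the list alone 9 rose and 6 fell. The median was 0.13, the mean -0.06 and the set adjusted p 0.407. Mast cell and basophil genes moved apart as well. CPA3 and the cytokine receptor gene IL1RL1 (2.26-fold) rose, while CLC, the Charcot-Leyden crystal protein, fell (log2 ratio -1.91 ± 0.08) and was well above background in knockdown RNA on 3 of 4 arrays. Of 12 genes in this list 3 rose, 6 fell and 3 did not pass (4 rose and 6 fell adjusted over the list alone), with a median of -0.12, a mean of 0.02 and a set adjusted p of 0.603. Of 15 granulocyte and monocyte genes 2 rose, 3 fell and 10 did not pass, as also adjusted over the list alone for rises and falls. S100A8 (-1.06 ± 0.61) and FCGR2A (-0.46) fell and CD33 (0.41) rose, and the set adjusted p was 0.489 at a median of -0.06. S100A8 was well above background in knockdown RNA on 2 of 4 arrays.

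Of 14 measured genes named as RUNX1 targets in earlier literature, 6 fell, 2 rose and 6 did not pass, with the same rises and falls adjusted over the list alone. CEBPA (-0.59 ± 0.13, SD, n = 2), GZMB (-0.49) and CCND3 (-0.41) fell most. Further CEBPA probes had -0.35 and 0.02, and a further CCND3 probe -0.20. The median was -0.03 and the set adjusted p was 0.426.

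**Figure D3:**
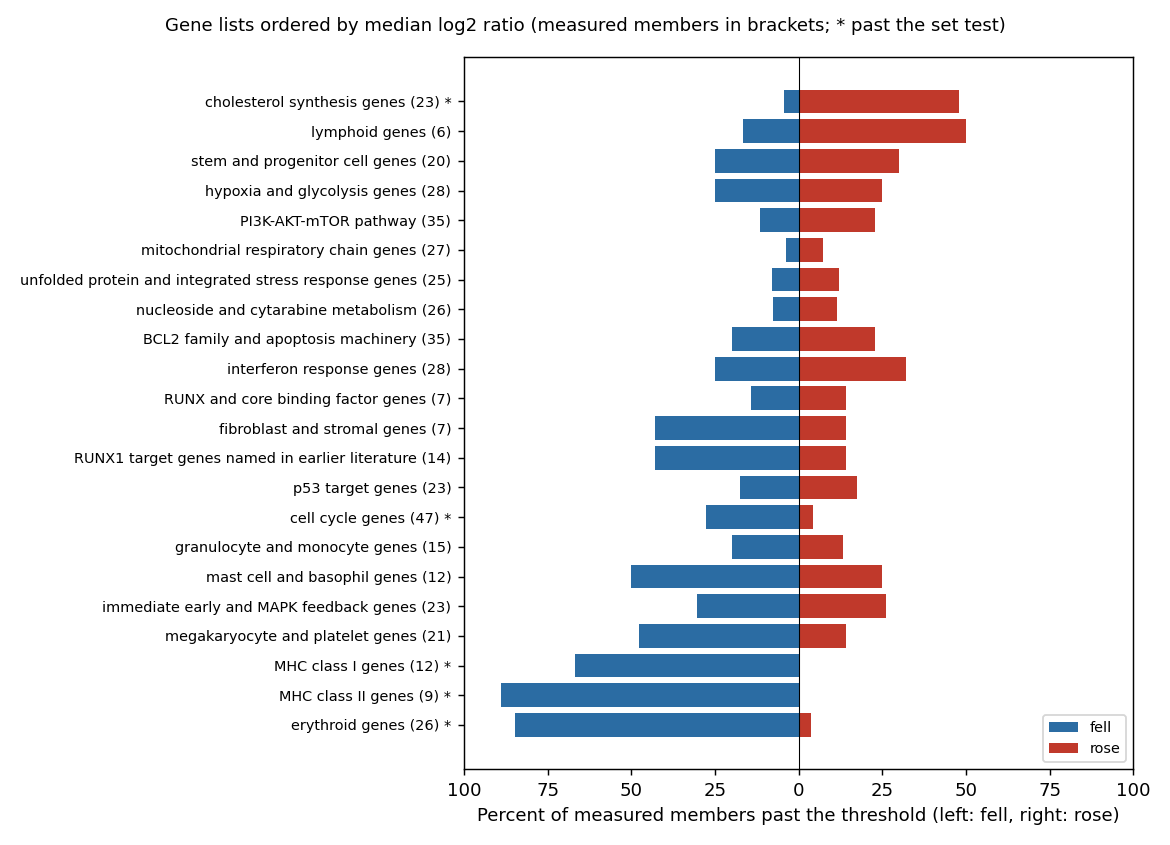
Percent of the measured members of each of the 22 gene lists that fell (bars to the left) or rose (bars to the right) past the adjusted p threshold, with lists ordered by their median log2 ratio. Erythroid and MHC lists have the longest bars on the falling side, and cholesterol synthesis genes rose more often (11 of 23) than they fell (1 of 23).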

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

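The alternative without the swapped array of pair 2, the brightest array, was chosen after seeing the data. All others were planned. The test against a 1.2-fold change was run for the counts only, not for single genes. RUNX1, by its brighter probe or the mean over its probes, was lower and past the threshold under the other alternatives with a test, with log2 ratios from -1.01 to -0.43 and adjusted p from 1.29e-17 to 0.00828. Without replicate 1 or 2 it was -0.997 to -0.75, as a value with no test. Of the other 81 named genes, 70 kept their side of the threshold in each of these tests. Of these, all but CBFB, which never passed, kept their direction. VIM reversed, from 0.37 to -0.25, on the arrays with knockdown RNA in the green channel alone. The remaining changes were 14 losses of a call, in FOXO3, SDHB, SDHD, CTH, TRIB3, SPARC, RRM2, PIK3CD and BCL2, and 2 gains, of RUNX2 with Agilent's processed signals and the series value table.

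Genes higher in knockdown numbered 1735 and moved to 2840 with median centring, 2954 with 4 arrays as if independent, 2648 with knockdown in the green channel alone, 1081 without the brightest array and 238 when tested against a 1.2-fold change. Genes lower numbered 2318 and moved to 1497 with median centring and 669 against a 1.2-fold change. Of the 4053 genes called, 3008 were also called with median centring and 2769 without the brightest array. With the pair as a random replicate block and a dye term, 1989 genes were higher and 2520 lower. The correlation within pairs used there (0.68) was computed from the contrasts, since limma's own function needs more arrays. The 198 genes changed at least 2-fold in both pairs became 451 with Agilent's processed signals and with the series value table, which are the same values, 105 with no background subtraction and 304 with every probe on its own, where 27460 probes were tested. The correlation of the pairs moved by less than 0.1 throughout.

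With an estimated correlation (adjusted p = 0.917) and with fry (adjusted p from 0.252 to 0.267) all 5 lists that passed lost the call. Over all 22 lists the lowest adjusted p was 0.917 with an estimated correlation and 0.252 with fry. With 2 pairs both tests rest on 1 residual degree of freedom. These losses thus do not tell whether correlation between genes weakens the calls. The medians were unchanged, at -0.69 for erythroid, -0.47 for MHC class II and -0.18 for MHC class I genes. They were 0.15 for cholesterol synthesis and -0.0529 for cell cycle genes. Fry does not compare a list with other genes. MHC class I genes also lost the call with median centring (median -0.0719), with knockdown in the red channel alone (-0.0712) and without the brightest array (-0.12). Cell cycle genes lost it with median centring (0.0686), red alone (-0.0736), green alone (-0.0716) and without the brightest array (-0.0438). Megakaryocyte genes gained a call with Agilent's signals and the series value table (-0.13) and with median centring (-0.0438). Except where a smaller set of arrays was used, the cause was not tested. With 1 slide and 1 scan, neither was run as a block. Signals near background limit dim genes: without background subtraction their ratios shrink.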

Other observations

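Other gene groups held strong changes that went both ways. Of 28 interferon response genes, 9 rose, 7 fell and 12 did not pass (10 rose and 10 fell adjusted over the list alone). IFI27 fell 6.45-fold (-2.69 ± 0.09, SD, n = 2) and RSAD2 1.98-fold, while IFIT1 rose 2.16-fold. The median was -0.01, the set test pointed upward, and its adjusted p was 0.822. Of 28 hypoxia and glycolysis genes 7 rose, 7 fell and 14 did not pass (11 rose and 7 fell adjusted over the list alone). EGLN1, the glucose transporter SLC2A1 (-1.21) and the enolase ENO2 (-1.03) fell, with a list median of 0.07, a mean of -0.13 and an adjusted p of 0.407. Of 23 immediate early and MAPK feedback genes 6 rose and 7 fell (6 and 8 adjusted over the list alone), with PHLDA1 at -1.38 ± 0.71 (further probes at -0.71, -0.39 and 0.10), CCND1 at -1.42 and DUSP6 at 0.63, a median of -0.13 and an adjusted p of 0.678.

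Of 23 p53 target genes 4 rose and 4 fell, as also adjusted over the list alone, with TIGAR at 0.66, TP53INP1 at -0.64 and PMAIP1 at -0.49 (median -0.03, adjusted p = 0.822). Of 25 genes of the unfolded protein and integrated stress response 3 rose and 2 fell (2 and 2 adjusted over the list alone), with the amino acid transporter SLC7A5 at -0.85 (a further probe at -0.05), TRIB3 at 0.24 and CTH at 0.21 (median 0.05, adjusted p = 0.331). Of 27 respiratory chain genes 2 rose and 1 fell (0 and 1 adjusted over the list alone), with COX4I1 at -0.51 (further probes at -0.47 and -0.06), SDHD at 0.19 and SDHB at 0.16 (median 0.05, adjusted p = 0.32). TRIB3, CTH, SDHD and SDHB lost their calls without the swapped array of pair 2, at log2 ratios of 0.21, 0.18, 0.19 and 0.17, CTH also on the arrays with knockdown in the red channel alone (0.15), and SDHD and SDHB also with every probe tested on its own, at unchanged ratios. Among markers of other cell types, 3 of 6 measured lymphoid genes rose and 1 fell, as also adjusted over the list alone, with CD79A at -0.47, PAX5 at 0.30 and RAG2 at 0.44, whose control RNA was well above background on 1 of 4 arrays (median 0.15, adjusted p = 0.407). Of 7 fibroblast and stromal genes 1 rose and 3 fell, as also adjusted over the list alone (median -0.02, adjusted p = 0.601). LUM, not well above background in knockdown RNA, was at least 1.73-fold lower, SPARC was at -0.27, a call lost with median centring (-0.13), and VIM was at 0.37 but at -0.25 on the arrays with knockdown in the green channel alone.

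The breakpoint search, the random sets and the other settings for chromosome 8 were chosen after the arm medians were seen. The other tests below were set out before. Copy number that differs between the colonies and the control pool was tested as the median of each chromosome arm with 50 or more tested genes. Of 40 such arms, the short arm of chromosome 8 lay farthest from 0, with a median log2 ratio of -0.21 (SE 0.031) over 154 genes, just beyond the size of 0.2 set in advance, of which 94 were called lower and 6 higher. The lowest median of 10000 random sets of that size was -0.06, but these sets do not allow for the arm being the farthest of 40. The fall was concentrated in the 113 tested genes from ZNF596 (185612) to TTI2 (33486992 to 33489085, hg17). Their median was -0.26 in pair 1 and -0.25 in pair 2, and 87.6% of them lay below 0. For the other 341 genes of the chromosome the median was 0.00 and 49.6% lay below 0. The end of the stretch was placed where it best parted these log ratios, so the contrast is partly built in. The arm median was also beyond that size with Agilent's processed signals (-0.21), but not with no background subtraction (-0.16) or with median centring (-0.12), so passing it depends on the processing. Relative to the median of all genes, the arm was at -0.25, -0.17 and -0.20 in these settings. A candidate explanation is a loss of distal 8p in the knockdown cells, or a gain in the pool. Whether the pairs hold different colonies is not stated in the labels, so their agreement does not show the change in more than a single colony. RNA ratios cannot tell these apart from a regional change of expression, and no DNA was measured.

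Loss of the short arm of chromosome 6 was set against the lower MHC genes. The other 406 tested genes of that arm had a median of 0.0073, against -0.29 over the 21 MHC list members, which argues against loss of the arm as the cause. A fall of both MHC transactivators may also lower these genes. CIITA fell by 0.18, but NLRC5 was not well above background and was not tested, so this stays open.

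A lower share of erythroid-like cells in the culture could lower erythroid genes by a common factor. Over the 25 members measured in both RNAs, the log2 ratios had an SD of 0.88, between the values set in advance for a common factor and against it, so this stays open. Sequence shared among globin and glycophorin probes does not account for the group, since the 17 other members had a median of -0.34 and 13 of them fell. A direct effect of RUNX1 was not tested, because only RNA levels were measured. Any effect of RUNX1 also cannot be told apart from the difference between colonies and pool.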
